A study of Mus musculus with 48 samples.

How the data were processed

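The series measured reporter DNA and RNA in 48 libraries of 24 biological samples, NSC and IPC of mouse somatosensory cortex collected at 5 ages. Samples were grouped by cell type and collection age from the labels. Per the submitters' processing notes, cutadapt (version not given) and the mouse build mm10 were used. The aligner, the counting of barcodes, the filters and the tool that made the activity values are not given in the sources used here.

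The deposited table holds 30 columns of values, 3 for each of 10 combinations of cell type and age, each combining 2 or 3 biological samples. The first is an activity score named statistic, which per the file headers and the values is never negative and on a linear scale. The header names are those written by the MPRAnalyze package, in which such a statistic is by default an estimate of RNA per DNA, but no source names that package, so the activity is treated as a score without a unit. The second, the authors' MAD score, was checked from the values: it is the statistic minus the median of the scrambled controls, divided by 1.4826 times their median absolute deviation (largest difference 4.66e-12). The third, the authors' deposited p-value, equals the upper-tail normal p of that score after Benjamini-Hochberg adjustment within the column (largest difference 6.11e-15). Because each comparison rests on values pooled by the authors, no test across biological samples was made. The tests planned for counts or for values per replicate were not run, and sizes and ranks against the scrambled controls take their place. The permutations of columns, the reshuffling of labels and the random gene lists replaced the planned limma, camera and fry tests of classes and lists, and were chosen after the table had been seen.

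The scrambled median differed between columns from 0.164 (NSC at E13) to 2.37 (NSC at E17), so each value was divided by the scrambled median of its column. The log2 of this ratio plus a pseudocount of 0.1 was taken, and the scrambled mean of the column was subtracted. Log2 differences near the pseudocount are therefore understated. Elements without a value in a column that a measure needs were left out of that measure, between 98 and 454 elements per column.

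Class values are means over elements per column. Cell types were compared by exact permutation of the 10 columns, with Benjamini-Hochberg adjustment over 6 comparisons. Age slopes are least-squares slopes per day over the 5 ages. The asc and desc labels were reshuffled 10000 times within deciles of mean activity. For single elements, non-scrambled elements were counted beyond limits that leave 2.5% of the scrambled controls on either side. Shares have 95% Wilson intervals, which cover the sampling of the counted elements only. The limits come from 955 to 990 controls, and the intervals leave out the uncertainty of the limits. Shares slightly above or below 2.5% are therefore not shown to differ from that of the controls. Depth is unknown. In simulated data with 10841 elements drawn from the scrambled controls and 200 changed, a shift of 2 on the log2 scale between cell types passed the limit in 74.0% of changed elements. A shift of 1 passed in 20.5% and a shift of 3 in 96.5%. Of the unchanged elements, 1.82% passed the upper limit and 1.76% the lower. They were drawn from the same controls as those that set the limits. These shares are therefore near 2.5% by construction and estimate no rate of false calls.

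Only names of E14 and Shadow elements carry coordinates, 1834 elements in all. They are printed as in the names, whose end minus start is 265. Each was assigned the protein-coding gene whose span holds it, or else the nearest span, from 21896 genes of the GRCm38.p6 annotation, the assembly behind mm10. The distance to a transcription start site named in the plan could not be computed, since strands were not used here. The NSC, IPC and Mature elements are not paired with genes in the files and are not named.

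The rule fixed before the data were examined named elements by an adjusted p across replicates, which pooled values cannot give. It was replaced, after values had been seen, by size and repeated direction: the 10 highest means, the 10 largest mean differences in each direction among elements with the same sign at all 5 ages, and the 5 steepest slopes in each direction and cell type among elements with both late ages beyond both E13 and E14. Not every element that the rule picks is printed. No elements were named for the difference of slopes. A stricter form, which also asked for the authors' adjusted p under 0.05 in at least 3 of the 5 columns of the higher cell type, was noted before the candidate elements were listed, left out of the rule, and tried again after they had been seen. It is given as an alternative only. Naming and gene lists were limited to E14 elements after it was seen that most Shadow elements share their coordinates. The comparison of E14 with Shadow elements was added at the same point. The rule covers native elements, and whether Shadow elements are native is not given. Counts of non-scrambled elements include Shadow elements. The planned comparison of motif-mutated with native elements was not run, since no element is named as mutated.

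The gene lists were neural stem cell, intermediate progenitor, deep-layer neuron, upper-layer neuron, pan-neuronal, early temporal, late temporal and glial, interneuron, Cajal-Retzius and non-neural. They describe where elements lie, not the expression of the cells. Lists with at least 5 E14 elements with a value in every column were set against 10000 random lists of E14 elements, matched on mean activity for differences and slopes. Alternatives were other pseudocounts, the MAD score scale, other centring, class medians, complete elements, other thresholds and limits, leaving out Shadow elements, and leaving out each age. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.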

Results

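A massively parallel reporter assay was carried out in the somatosensory cortex of C57BL/6JRj mouse embryos. In such an assay, many short DNA elements are placed in reporter plasmids, and the RNA that each element drives is set against the DNA of the plasmids that reached the cells. The plasmid library was electroporated in utero on embryonic day (E) 12, 13, 14, 15 or 16, and cells were collected 24 h later, at E13 to E17. Pax6-positive neural stem cells (NSC) and Tbr2-positive intermediate progenitors (IPC), the dividing daughters of neural stem cells that produce neurons, were sorted from each age. The 48 libraries comprised 24 biological samples, each with a DNA and an RNA library, with 3 biological samples per cell type at E14 and E15 and 2 at E13, E16 and E17.

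The deposited table gave 1 activity value per element for each of the 10 combinations of cell type and age, so the spread between biological samples is not known and no element was tested across them. It held 11709 elements: 996 scrambled controls and 10713 others, labelled NSC (3125), IPC (2991), Mature (2763), E14 (931) and Shadow (903). What these names stand for is not given in the sources used here beyond the names themselves. Read and barcode numbers were not used here, so the depth behind each value is unknown. Between 11255 and 11611 elements had a value in a column. Activities below are log2 values relative to the scrambled controls of the same column, and a standard error (SE) given with a class mean is over elements, not over animals.

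Elements of the NSC class were the more active in neural stem cells, and elements of the IPC class the more active in intermediate progenitors. In NSC columns the NSC class averaged 0.24 above the scrambled controls over the 5 ages and the IPC class 0.11. In IPC columns the NSC class averaged 0.06 and the IPC class 0.23. The NSC class stood above the IPC class at all 5 ages in NSC columns, by 0.08 at E13 to 0.20 at E17, and below it at all 5 ages in IPC columns, by -0.14 at E13 to -0.20 at E17. The gap between the classes thus changed by -0.31 from NSC to IPC columns (exact permutation test of the 10 columns into 5 and 5, two-sided p = 0.00794, the smallest that 252 splits allow; Benjamini-Hochberg adjusted p = 0.0238 over 6 comparisons). The test takes ages as the observations and ignores that NSC and IPC columns share them. Paired by age, exact sign flips of the 5 differences allow no p under 0.0625 and gave an adjusted p of 0.075. With 1 age left out of both cell types the change was -0.33 to -0.28; the exact permutation adjusted p was 0.0429 without E13, and 0.0686, 0.0857, 0.0571 and 0.0571 without E14, E15, E16 and E17.

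**Figure D1:**
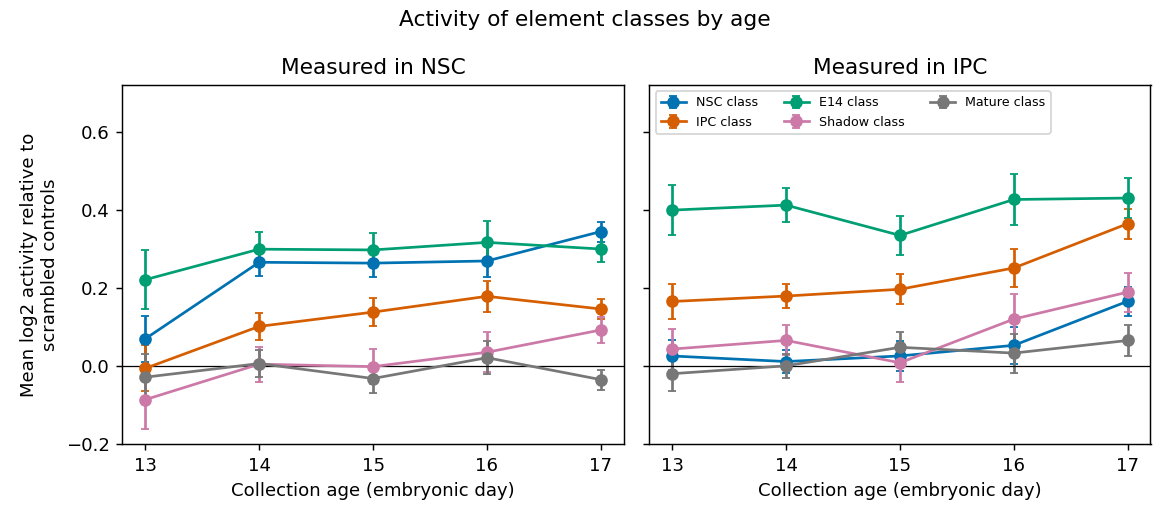
Mean log2 activity relative to the scrambled controls (vertical axis) of 5 element classes against collection age in embryonic days (horizontal axis), in NSC (left) and IPC (right); bars are the SE over elements. The NSC class lies above the IPC class at each age on the left and below it at each age on the right.

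Taken class by class, activity in IPC minus that in NSC was -0.19 for the NSC class, with NSC higher at 5 of 5 ages (exact permutation p = 0.0159, adjusted p = 0.0238). It was 0.12 for the IPC class (exact permutation p = 0.0159, adjusted p = 0.0238) and 0.11 for the E14 class (exact permutation p = 0.00794, adjusted p = 0.0238), both with IPC higher at 5 of 5 ages. The Shadow class (0.08, exact permutation adjusted p = 0.111) and the Mature class (0.04, exact permutation adjusted p = 0.0952) did not pass, though Shadow elements too were higher in IPC at 5 of 5 ages and Mature elements at 4. Paired by age, the NSC, IPC, E14 and Shadow classes had an adjusted p of 0.075 (exact sign flips). One sign at 5 of 5 ages gives this value by construction, so it cannot tell them apart. The NSC, IPC and E14 differences each lost their call when E14, E15, E16 or E17 was left out (exact permutation adjusted p 0.0571 to 0.0857). Without an age only 70 splits of the columns remain, so the loss can come from the smaller design alone. The differences of these classes did depend on the summary used. With class medians in place of means they were -0.21, 0.06 and 0.04 for the NSC, IPC and E14 classes. The exact permutation adjusted p was 0.143, 0.886 and 0.886. With medians the gap between the NSC and IPC classes changed by -0.27 (exact permutation adjusted p = 0.0476).

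The E14 class held the largest share of active elements. Averaged over the 5 ages, 21.3% of its elements in IPC (95% Wilson interval 18.8 to 24.1) and 10.6% in NSC (8.71 to 12.7) exceeded an upper limit that 2.5% of the scrambled controls exceed by construction. In the IPC class 12.3% exceeded it in IPC and 4.59% in NSC. In the NSC class 5.32% did so in IPC and 9.16% in NSC. The Mature class had 4.51% in IPC and 3.56% in NSC, and the Shadow class 6.53% and 2.87%. Over all non-scrambled elements, 865 of 10051 (8.61%) exceeded the limit in IPC and 615 of 10162 (6.05%) in NSC. The limits were 0.98 in IPC and 1.06 in NSC.

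**Figure D2:**
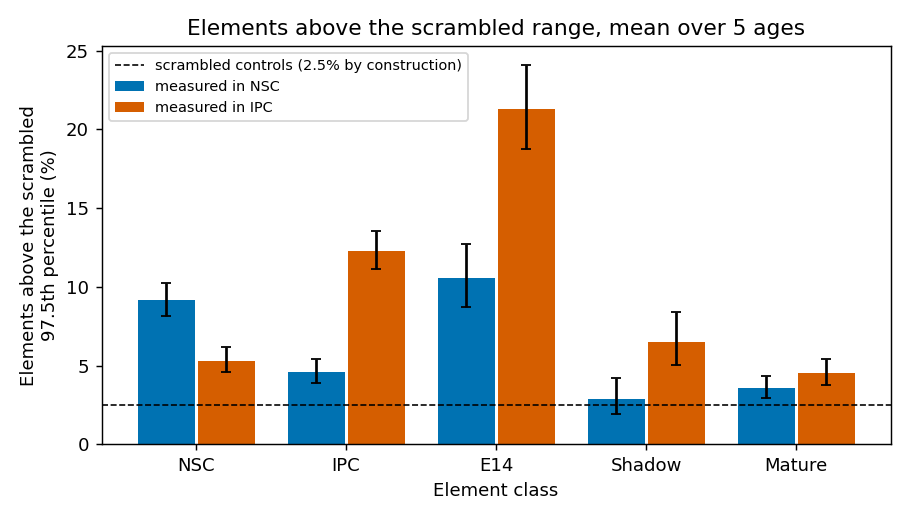
Share of elements (percent, vertical axis) whose mean activity over 5 ages exceeded the limit that 2.5% of the scrambled controls exceed, for 5 element classes in NSC (blue) and IPC (orange); bars are 95% Wilson intervals and the dashed line is the 2.5% of the controls. The E14 class reached 21.3% in IPC and 10.6% in NSC.

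The authors' own adjusted p-values, which compare each element with the scrambled controls of its column, fell under 0.05 for 11.3% (IPC at E14) to 19.6% (IPC at E13) of non-scrambled elements. The same threshold took in 6.16% (NSC at E17) to 15.7% (IPC at E13) of the scrambled controls themselves. Calls repeated over ages separated the groups further, but not evenly over classes. In at least 3 of the 5 IPC columns, 15.1% of E14 elements were called, 5.00% of all non-scrambled elements and 1.20% of scrambled controls. In NSC columns the shares were 9.02%, 4.66% and 1.31%. The Mature class stood at 2.17% in IPC and 2.21% in NSC columns, and the Shadow class at 4.32% and 1.77%. In total, 499 non-scrambled elements were called in at least 3 NSC columns and 536 in at least 3 IPC columns.

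Single elements could be placed in the genome for the E14 class, whose names carry mm10 coordinates. Of these 931 elements, 56.8% lay within the span of a protein-coding gene in the GRCm38.p6 annotation. Exons, introns and strands were not used here, so a gene name below gives location, not the gene an element regulates. The E14 element of highest mean activity over the 10 columns lay within Pax6, the transcription factor used to sort the neural stem cells (chromosome 2, 105686827 to 105687092), at 2.03 in NSC and 2.05 in IPC. It was followed by elements 11.63 kb from Kcng1 (2.01 over all columns), within Nos1ap (1.85), within Ttc28 (1.84), 96.87 kb from Ust (1.80), within Sdc3 (1.78), within Rps6ka2 (1.76), within Dusp10 (1.76), within Atrnl1 (1.74) and within Afap1 (1.74). The order depends on E13, where the Pax6 element stood at 3.87 in NSC and 4.73 in IPC. Without E13 it stood at 1.47, below 7 of the other 9 elements named here, of which the element within Dusp10 was highest (2.04).

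Between the cell types, 509 of 9886 non-scrambled elements (5.15%) exceeded the upper scrambled limit for the mean difference over ages (1.22). They were thus higher in IPC, and 298 (3.01%) lay under the lower limit (-1.41). Counted by the same sign at all 5 ages, 435 (4.40%) were higher in IPC and 408 (4.13%) in NSC. The imbalance beyond the limits shrank without E15, to counts of 404 and 394, and without E16, to 357 and 330, each against limits drawn anew. The classes differed in direction. E14 elements lay above the upper limit most often (12.04%). Below the lower limit, E14 (4.84%, Wilson interval 3.61 to 6.45) and the NSC class (4.32%, 3.64 to 5.13) were not told apart. The NSC class had 78 elements above and 125 below, and the IPC class 189 and 51. By the same sign at all 5 ages, the NSC class had 57 elements higher in IPC and 186 (6.43%) higher in NSC. The IPC class had 173 and 74. The counts over all non-scrambled elements mix these opposite directions. For all non-scrambled elements, shares were also taken at single ages. Those above the limit were 3.63% at E13, 3.83% at E14, 2.87% at E15, 4.54% at E16 and 4.60% at E17, against 2.5% of controls. The shares below were 2.83%, 3.74%, 3.57%, 4.11% and 3.28% at the same ages. At E15, 369 elements lay below the lower limit of -2.59 and 297 above the upper limit of 2.84. Over all ages and at E13, E14 and E15, the side with the nearer limit held more elements. At E16 and E17 it did not. The limits were -3.13 and 3.19 at E16, with 417 elements below and 461 above. They were -2.30 and 2.41 at E17, with 345 below and 484 above. The counts over all ages therefore do not settle which direction was the more frequent.

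Among E14 elements, 83 of 889 (9.34%) were higher in IPC at all 5 ages and 44 (4.95%) were higher in NSC at all 5. The shares among scrambled controls were 2.62% and 3.14%, so part of each list is to be expected without any difference. The largest such mean difference towards IPC among E14 elements was that of an element within Mmp24, which encodes a membrane-bound matrix metalloproteinase (chromosome 2, 155788662 to 155788927). It stood at -0.37 in NSC and 2.60 in IPC, with differences of 0.58 to 5.10 between ages. Next came elements within Cacna1s (2.56), Ccdc13 (2.52) and Fbrsl1 (2.51), 75.73 kb from Dusp4 (2.36), within Slc39a11 (2.27), within Cacna2d1, a calcium channel subunit gene (2.19), near Ust (2.16), within Dpysl5, a collapsin response mediator gene of growing axons (2.14), and within Efcab6 (2.13). Without E13 the differences within Cacna1s and Ccdc13 were 1.63 and 1.58. Of these 10 elements, 7 were called by the authors' adjusted p in all 5 IPC columns. That p is computed from the same values that picked the elements, so such calls were largely given by the choice.

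Among E14 elements of the same sign at all 5 ages, the largest mean difference towards NSC was that of an element 31.28 kb from Ercc6l2 (chromosome 13, 63779438 to 63779703), at 2.68 in NSC and 0.02 in IPC, a difference of -2.65. Without E13 the difference was -1.72, smaller than those of 8 of the other 9 elements named here, with the element near Dcakd at -3.04. The element near Ercc6l2 was called in 5 of 5 NSC columns and in 0 IPC columns. IPC minus NSC was -2.53 for an element 126 bp from Dcakd, -2.53 within Gabrb1, a GABA-A receptor subunit gene, -2.24 at 82.89 kb from Foxd3 and -2.18 within Tenm3. The differences were -1.99 for an element 104.1 kb from Nebl, -1.90 within Dlgap2, which encodes a postsynaptic scaffold protein, -1.77 near Arhgef26, -1.71 near Blcap and -1.70 near Acad8. Of these 10 elements, 3 were called by the authors' adjusted p in all 5 NSC columns. Here too the calls come from the values that picked the elements and are no separate support.

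**Figure D3:**
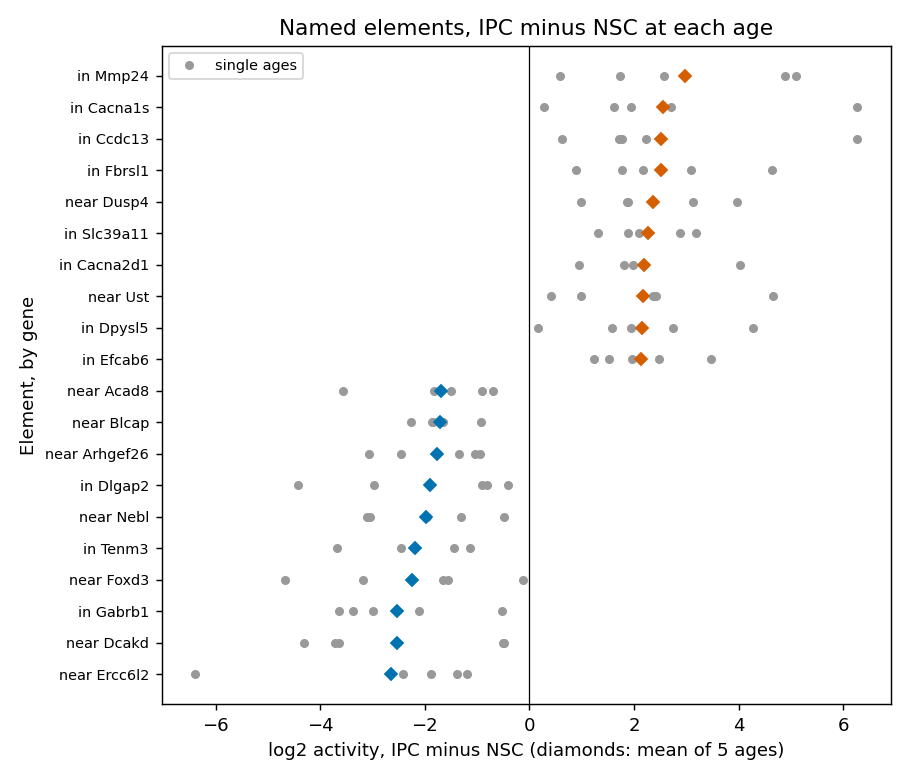
Log2 activity in IPC minus NSC (horizontal axis) of the 20 E14 elements named for the cell type difference (vertical axis, by the gene they lie in or nearest to); grey points are the 5 ages and diamonds their mean, orange for higher in IPC and blue for higher in NSC. The 5 ages of an element spread widely, for example from 0.58 to 5.10 for the element within Mmp24.

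E14 elements were more active than Shadow elements of the same coordinates. Of the 903 Shadow elements, 844 carried exactly the coordinates of an E14 element; whether their sequences differ is not given in the sources used here. The E14 member of a pair was higher on average in 10 of 10 columns, by 0.22 (NSC at E17) to 0.39 (IPC at E13). Over the ages the difference was 0.29 ± 0.03 (SE over 792 pairs) in NSC and 0.33 ± 0.03 (SE over 777 pairs) in IPC, above all of 10000 random swaps of the labels within pairs. The change of this difference between cell types, 0.05 ± 0.04 (SE over 759 pairs), lay at the 86.6th percentile of such swaps. Activity over all columns did not go together within pairs (Spearman's rho 0.02 across pairs). Between odd and even ages, rho was 0.35 across E14 elements and 0.13 across Shadow elements. These values and the difference in 10 of 10 columns argue against the same sequence in both members of a pair. How the members differ is not given. The element within Pax6 stood at 2.04 over all columns, and its Shadow counterpart at -0.20.

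Activity changed with age in the NSC class according to a label in the element names. NSC elements labelled asc went from 0.01 at E13 to 0.46 at E17 in neural stem cells. Those labelled desc stood at 0.05 at E13, peaked at 0.28 at E14 and fell at each later age, to 0.16 at E17. What asc, desc and unc stand for is not given in the sources used here. The mean slope per day was 0.10 ± 0.01 (SE, 1094 elements) for asc and 0.02 ± 0.01 (SE, 1019 elements) for desc. Their difference of 0.09 exceeded all of 10000 reshufflings of the labels among elements of similar mean activity. Such percentiles, here and below, cover the sampling of elements only. Each age is a single pooled column, so they cannot tell an age trend from a column effect that differs between labels. In intermediate progenitors the same elements differed by 0.01 per day (69.0th percentile), and the difference between cell types, 0.07, lay at the 99.98th percentile. Without E17 the asc minus desc slope in neural stem cells was 0.06, at the 96.8th percentile, and its difference between cell types was at the 97.45th, so both lost their call. NSC at E17 is also the column whose scrambled median (2.37) and spread (1.02) stood apart from the other NSC columns. Relative to the median, however, its spread was the lowest of all columns (0.43). That of NSC at E13, where the rise starts, was the highest (1.05).

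**Figure D4:**
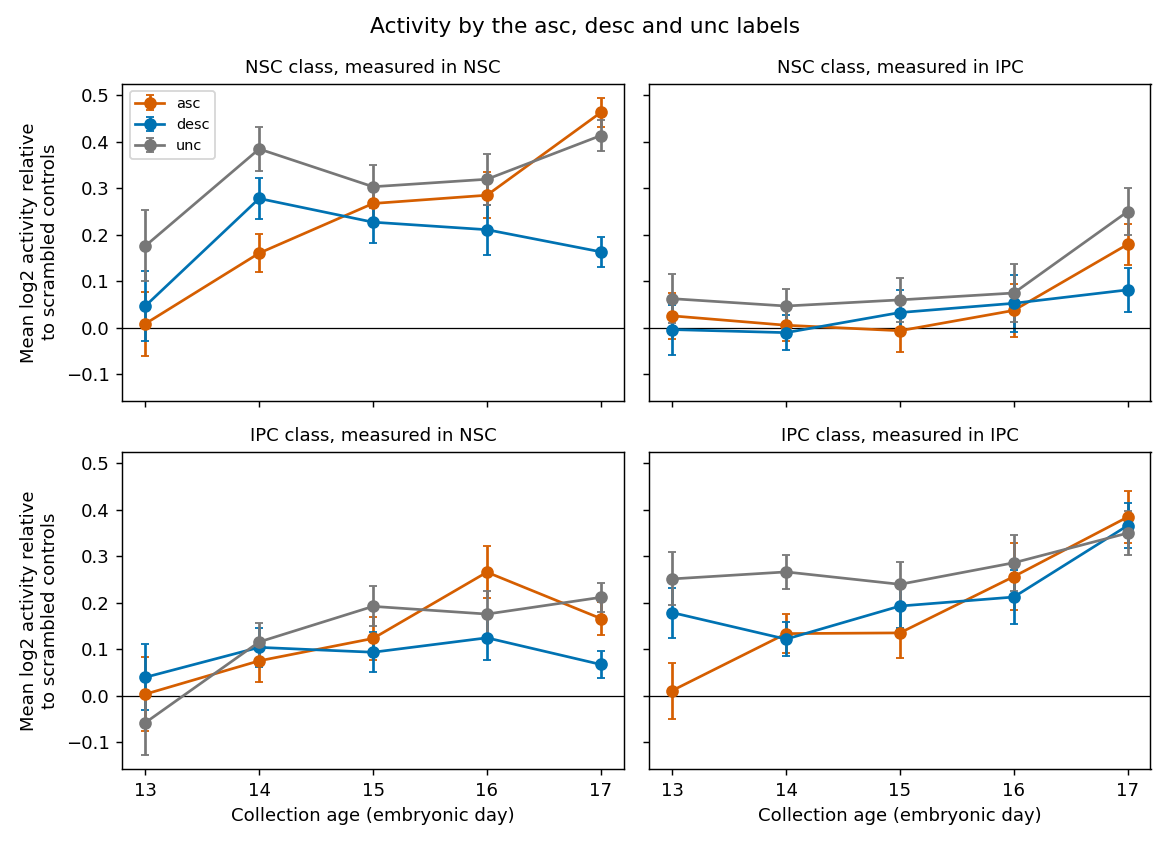
Mean log2 activity relative to the scrambled controls (vertical axis) against collection age in embryonic days (horizontal axis) for elements labelled asc, desc and unc of the NSC class (top) and IPC class (bottom), in NSC (left) and IPC (right); bars are the SE over elements. At top left, asc goes from 0.01 to 0.46, and desc from 0.05 to a peak of 0.28 at E14 and down to 0.16.

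IPC elements labelled asc went from 0.01 at E13 to 0.38 at E17 in intermediate progenitors, and those labelled desc from 0.18 to 0.37, with 0.21 still at E16. The slopes differed by 0.06 per day in IPC (99.92nd percentile) and by 0.04 in NSC (99.94th percentile), and the difference between cell types was within the reshuffled range (27.0th percentile). Without E13 the difference in IPC was 0.03, at the 85.9th percentile. Elements labelled unc did not lie between the other labels in IPC columns, with slopes of 0.016 for unc, 0.040 for desc and 0.096 for asc. In NSC columns unc (0.056) was near asc (0.058), with desc at 0.014. For the NSC class in NSC columns, unc lay between, at 0.047. In the Mature class the asc minus desc slope went the other way in NSC, at -0.10 (0.04th percentile), and was -0.03 in IPC (25.4th percentile). Without E16 the difference in NSC was -0.08, at the 4.25th percentile.

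Single elements beyond the scrambled limits for a change with age were more frequent in IPC, where the limits were narrower. By construction, 2.5% of the controls lie beyond each limit. The slope limits were -0.81 and 0.67 in NSC and -0.67 and 0.63 in IPC. Those for E17 minus E13 were -3.92 and 2.93 in NSC and -3.27 and 2.60 in IPC. The higher shares in IPC therefore do not show that changes with age were more frequent there. The slope over E13 to E17 lay above the scrambled limits for 3.33% of non-scrambled elements in NSC and 4.56% in IPC, and below them for 2.46% and 3.86%. E17 minus E13 lay above the limits for 3.64% in NSC and 5.73% in IPC and below them for 2.21% and 3.16%. The difference of the slopes between cell types lay above for 3.39% and below for 3.58%. In NSC, the limits for the slope caught 18.5% of elements with a simulated slope of 0.5 per day, so most NSC slopes of that size would be missed. The other age measures were not simulated.

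The E14 elements named for age trends are given as values. Elements with E16 and E17 both above E13 and E14 made up 20.2% of E14 elements in NSC and 19.1% in IPC, against 17.7% and 18.3% of scrambled controls. Those with both late ages below both early ones made up 17.7% and 19.3%, against 15.4% and 16.02%. Slopes per day in NSC were highest near Sfr1 (1.13), within Dnajb14 (1.04), near Moxd1 (0.94), within Vcam1 (0.93) and near Dapl1 (0.90). They were lowest within Nav2 (-1.52), near Lamp5 (-1.49), within Nos1ap (-1.23), near Gm42323 (-1.16) and near Gm829 (-1.01). Several rest on few columns. Without E13 the slopes were 0.14 within Vcam1, 0.69 within Dnajb14, -0.64 within Nav2 and -0.51 within Nos1ap. Without E16 they were 0.72 near Sfr1 and 0.55 near Dapl1. Without E17 they were 1.75 near Sfr1, 1.74 within Vcam1, 1.65 near Dapl1, -1.85 within Nos1ap and -1.87 near Gm42323. In IPC the slopes were highest near Srrm4 (1.46), near Cxcl12 (1.33), within Prdm16, a transcription factor gene of radial glia (1.26), near Cntn5 (1.15) and within Csrp1 (1.12). Among the lowest were those within Slc39a11 (-1.82), near Aff3 (-1.80), near Gm7932 (-1.31) and near Ptpn20 (-1.28). Without E13 they were 0.61 near Cxcl12, 1.98 within Prdm16 and -0.75 near Aff3, and without E17 0.67 near Cntn5, 0.44 within Csrp1 and -2.76 near Aff3. Some slopes also depended on the pseudocount. The element near Cxcl12 stood at -3.62 in IPC at E13. Its slope was 0.86 with a pseudocount of 0.5 and 1.89 with 0.01. The NSC slope within Dnajb14 was 0.67 and 1.31 with the same settings.

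Of the gene lists fixed before the data were examined, the pan-neuronal list was the only 1 of 3 tested whose activity level lay outside the central 95% of random lists. Its 8 E14 elements averaged 1.10 in IPC and 0.30 in NSC, and the IPC level was at the 98.8th percentile of 10000 random lists of the same size. Of the 8, 3 were higher in IPC at all 5 ages and 0 were higher in NSC at all 5. Elements nearest to Sox11, a transcription factor gene of new neurons, stood at 2.42 and 2.10 in IPC against 0.50 and 0.60 in NSC, but lay 326.9 and 495.8 kb from it. An element 7.931 kb from Neurod2, a neuronal transcription factor gene, stood at 1.44 in IPC and 0.02 in NSC. An element within Rbfox3, whose product is the neuronal antigen NeuN, stood at 1.50 and -0.22. These 4 are the highest of the list by mean over all columns. The other 4 averaged 0.34 in IPC and 0.37 in NSC, with no excess in IPC. Their lower level is given by construction, and no random list was split in this way. The mean difference of the list, 0.80, was at the 97.0th percentile, inside the central 95%. Of 15 such percentiles computed over 3 lists, 2 lay outside the central 95%, where chance gives 0.75.

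The neural stem cell list had 15 E14 elements, with a mean of 0.39 in NSC (73.2nd percentile) and 0.45 in IPC (57.4th percentile). Besides the Pax6 element, an element 63.79 kb from Hes1, a Notch target gene, stood at 1.31 in NSC and 1.41 in IPC. The 11 elements of the list beyond its 4 highest averaged 0.10 in NSC and 0.11 in IPC. Such a remainder, here and in the next list, is lower by construction, since the 4 were picked by these same values. No random list was trimmed in this way. The 12 elements of the late temporal and glial list that had a value in every column averaged 0.24 in NSC (40.1st percentile) and 0.22 in IPC (18.6th percentile), and the 8 beyond its 4 highest averaged -0.10 and 0.07. Their mean slope in IPC was -0.20 per day, at the 2.47th percentile, the only list slope outside the central 95%. An element within Nfia, a gliogenic transcription factor gene, stood at 1.88 in NSC and 0.41 in IPC, but these means rest on single columns, with 5.51 in NSC at E13 and -3.28 in IPC at E16. The other lists had too few E14 elements to be set against random lists: 3 for intermediate progenitor, deep-layer neuron and early temporal genes, 5 for upper-layer neurons, of which 4 had a value in every column, 1 for interneurons, without a value in every column, 1 for Cajal-Retzius cells and 0 for non-neural genes. Among these, the element 1.737 kb from Eomes, which encodes Tbr2, stood at -0.28 in NSC and 0.25 in IPC, and an element within Hmga2, an early progenitor gene, at 2.35 and 1.11.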

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

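Apart from the scoring of scrambled controls on the log2 scale, the tests of explanations in this part were chosen after the result was seen. Of 28 groups of 5 columns examined for a value far from the others, 6 had one, where chance gives about 1.4.

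The scale of the activity score differed between columns. The scrambled median was 2.37 in NSC at E17, where the nearest other NSC column stood at 0.537, and 1.59 in IPC at E14, where the nearest other IPC column stood at 0.556. The scrambled spread in NSC at E17 was also far from the others, at 1.02 against 0.282. A single scale factor per column argues for an unchanged ratio of spread to median, yet both columns of highest level, 2 of 2, were those of lowest ratio. A fuller sampling of the library in those columns could give both, but the number of elements without a value went with the scrambled median only at a Spearman's rho of -0.353 over 10 columns (permutation p = 0.316; Pearson's r = -0.548, permutation p = 0.113, with r at 0.0857 once the 2 columns farthest from the median are left out). It stays open, and no biological explanation was tested.

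Scrambled controls were called active by the authors' adjusted p in 6.16% to 15.7% of cases. A right-skewed spread scored with a normal p may account for part of this. On the log2 scale the share fell to 2.5% or less in 7 of 10 columns, but the bound set beforehand for the whole cause was 8, and IPC at E13 kept 6.80%. Calls among the other elements fell as well, from between 11.3% and 19.6% to between 0.316% and 9.33%, so the fall is not particular to the controls. Activity of some scrambled sequences themselves stays open: 26 were called in at least 4 columns against 14.9 in reshuffled columns, while their rank correlation between odd and even ages was 0.357 times that of the other elements, with a bootstrap interval of 0.0617 to 0.675 on either side of the bound.

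NSC and IPC columns of the same age resembled each other. Across non-scrambled elements the mean rank correlation of same-age pairs was 0.112, higher than in any other of 120 matchings of ages. Age-dependent activity of genomic sequences as the whole cause is argued against by the scrambled controls, where a share of only 0.025 of the matchings was as high. A technical origin shared by both sorts of an age is a candidate explanation: the excess in scrambled controls was 0.777 times that in the other elements, but with a bootstrap interval of 0.206 to 1.69 this stays open. The sources used here do not say whether both cell types came from the same embryos.

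Further values far from the other columns were the NSC class mean in IPC at E17 (0.166, nearest other 0.0532), the E14 class mean in NSC at E13 (0.221, nearest other 0.298) and asc minus desc of the Mature class in IPC at E16 (-0.238, nearest other -0.0654). The gap between NSC and IPC classes differed between cell types by -0.306 (exact permutation adjusted p = 0.0238). The asc minus desc slope differed between NSC and IPC by 0.0722 per day in the NSC class (99.98th percentile of reshuffled labels), a call lost without E17 (97.45th percentile). In the Mature class it differed by -0.0763 (1.77th percentile), but by -0.00258 without E13 (38.25th percentile), and the call was also lost without E16 and with a pseudocount of 0.5.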

How the results depend on the processing

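No paired analysis was possible between biological samples, because each deposited value combines the biological samples of a cell type and age. For the same reason the planned limma, edgeR and DESeq2 fits, the F test over ages, fits of 1 cell type alone, the count filters and leaving out single biological samples were not run. Chosen after seeing the data were the pseudocounts, the MAD score scale, centring on all elements, the wider limits, leaving out ages or Shadow elements, and pairing by age. Pairing aside, of 461 values of the main comparisons under an alternative, 393 kept their side of the threshold or, for counts, stayed within 1.5 times, 31 lost a call, 36 counts moved by more than 1.5 times and 1 reversed a called difference. Among the 393, 2 slope differences that were not called changed sign: NSC minus IPC of the IPC class without E13 (0.0170) and the NSC class in IPC without E17 (-0.0204). Named elements kept their sign in all 448 values, of which 23 moved by more than 1.5 times in size. They were named for size and repeated direction, so a kept sign was largely given in advance. Leaving out Shadow elements, 903 of the 10713 non-scrambled ones, moved no count by more than 1.5 times. With values left as deposited or centred on all elements, each column shifts by a constant that cancels against the scrambled limits. The counts among the 393 from these settings therefore could not change.

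The change of the NSC to IPC class gap between cell types passed under each setting except pairing by age and when E14, E15, E16 or E17 was left out; its range without an age was -0.328 to -0.283. Without an age only 70 splits of the columns remain. Values left as deposited and centring on all elements shift whole columns, so the size of the gap is unchanged by construction. Leaving out ages gave -0.222 to -0.169 for IPC minus NSC in the NSC class, 0.0950 to 0.135 in the IPC class and 0.0976 to 0.133 in the E14 class, each losing its call without E14, E15, E16 or E17. Single-class differences lost their call in other settings too. The IPC class stood at 0.122 with a pseudocount of 0.01 and the E14 class at 0.120 on the MAD score scale. Centring on all elements gave -0.149 for the NSC class. Class medians gave -0.209, 0.0623 and 0.0364 for the NSC, IPC and E14 classes. The cause was not tested. With values left as deposited, which keeps the unequal column scales, these were 0.0269, reversed, 0.333 and 0.327. Pairing the columns by age allows no p under 0.0625, so no class difference can pass; the gap and the NSC, IPC, E14 and Shadow classes had an adjusted p of 0.075.

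Without an age, the asc minus desc slope of the NSC class was 0.0551 to 0.123 in NSC, and 0.0615 to 0.0868 for NSC minus IPC; both lost their call without E17 only. That of the IPC class in IPC was 0.0258 to 0.0790, lost without E13. That of the Mature class was -0.151 to -0.0606 in NSC, lost without E16, and -0.129 to -0.00258 for NSC minus IPC, lost without E13 or E16 and, at -0.0631, with a pseudocount of 0.5.

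Limits that leave 0.5% of the controls on either side lower each count by construction. Active elements were then 216 in NSC and 419 in IPC. Elements higher and lower were 184 and 92 for IPC against NSC over all ages, 132 and 62 for the NSC slope, 143 and 110 for the IPC slope, and 122 and 50 for the slope difference. For E17 against E13 they were 87 and 54 in NSC and 176 and 74 in IPC. For IPC against NSC they were 121 and 46 at E13, 173 and 82 at E14, 49 and 159 at E15, 170 and 74 at E16, and 142 and 76 at E17. An adjusted p threshold of 0.01 left 291 elements called in at least 3 NSC columns and 357 in at least 3 IPC columns. With 4 columns in place of 5 these counts were 227 to 279 and 277 to 335. Depth is unknown, so what it limits was not assessed.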

Other observations

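Agreement between columns across elements was low. Spearman's rho between pairs of columns ranged from 0.0297 to 0.191 across non-scrambled elements and from -0.0461 to 0.188 across scrambled controls, and elements are not independent replicates.

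The stricter naming rule, tried after the candidates were seen, left 59 of the 83 E14 elements higher in IPC and 17 of the 44 higher in NSC. Among 955 scrambled controls it left 0 of 25 and 3 of 30.

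Mature elements stayed near the scrambled controls, with class means from -0.03 to 0.07 over the 10 columns. Among them, the elements labelled asc stood at 0.18 in NSC at E13 and at -0.13 at E16.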
